A study of Mus musculus with 3 samples.

How the data were processed

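Neocortical total RNA of 3 wild-type CD1 mice at postnatal day 13 was extracted with Trizol, labelled with biotin by the Affymetrix whole-transcript sense target assay and hybridised to 1 array per animal, per the labels' protocols. The 3 arrays are biological replicates of 1 group, per the series' design text. The p-value of the variance test sets a probe set's spread between these animals against that of other probe sets of like level. The p-value of the list test ranks a list against random lists of genes. The deposited values are probe set intensities on a linear scale. Affymetrix Power Tools and genome build mm8 are named in the submitters' processing notes. The background correction, normalization and probe set summary are not given in the sources used here. The lower quartiles of the deposited intensities were 51.4, 49.9 and 43.8 and the upper quartiles 952.5, 1087 and 998.7, so the probe set values of the arrays do not share 1 distribution, and differences between arrays in overall brightness remain in them. Values ran from 0.00031 to 18243, and 433, 445 and 531 probe sets lay under 1, where a small difference in intensity becomes a large one on the log2 scale.

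Log2 of each deposited intensity was taken with no pseudocount. Gene names came from the platform annotation: 14938 probe sets had 1 gene symbol, 989 had several and were given no gene, and 7245 are unnamed here. Of the single-gene probe sets, 14883 were found by Entrez ID in a RefSeq table of assembly GRCm38, which changed 0 symbols and served to match older symbols, for the order of genes and for genomic spans. No coordinates are given, since that assembly is not the build of the arrays' processing. Where a gene had several probe sets (131 genes), the one with the highest mean was used.

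With 1 group and no control tissue, background was taken from genes that cortex is not known to use. The limit of each array was the 95th percentile of the log2 values of 951 probe sets for olfactory, vomeronasal and trace amine receptors: 6.86, 6.71 and 6.69, or intensities of 116.0, 105.0 and 103.3. A probe set was called above the limit only if it exceeded it on all 3 arrays. This held for 13811 of 23172 probe sets, for 74.6% of the single-gene ones and 30.1% of the unnamed ones, and for 31 of the 951 receptor probe sets. Other probe sequences can have other backgrounds, so the limit is a guide and not a detection test.

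Before the data were examined, 42 lists of 487 genes were fixed: markers of cortical and neighbouring cell types, cellular programs, and tissues outside the brain. Of these genes 390 were measured, and 41 lists had at least 3 measured genes. The level of a list was the median of its members' means, set against 10000 random lists of as many measured genes. Many of these genes were chosen because brain is known to express them, and the probes of a list differ from those of random lists, so a percentile is a description of these arrays. The spread between mice was tested per probe set with limma 3.58.1 (fitFDistRobustly with a trend on the mean) in R 4.3.3, as the upper tail of an F distribution for the variance of the 3 arrays, over the 13811 probe sets above the limit, with Benjamini-Hochberg adjustment. The prior had 21.2 degrees of freedom. On simulated data for this test with 13811 probe sets, 39% of 100 genes with a 4 times larger SD and 81% of 100 genes with an 8 times larger SD were recovered, with 2 false calls. For each list, the range over mice of its members' median deviation was set against 10000 random lists matched on mean level in 20 bins, one-sided, with Benjamini-Hochberg adjustment over 41 lists. On simulated data with 40 lists of 11 genes, 5 of 5 lists shifted by 0.4 on 1 array were recovered with 0 false calls. Both simulations drew genes independently from the fitted variance model, with no correlation within a list and no offset shared by an array. Recovery and false calls on the real arrays can therefore differ. The genes of a list are not independent, so the p-value of a list describes these 3 arrays and is not a test over animals. The smallest p the list test can give is 0.0001.

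The genes named were set by rule before the data were examined: the first 4 measured genes of each list in its written order, further members only if they passed the variance test, all named probe sets past that test up to 25, and the measured sex-linked genes. For brevity fewer than 4 are named for some lists. Ptgds, Mgp, Kdr, Cox6a1, S100a8, S100a9, Camp, Glo1, Btbd9, Dnah8 and Glp1r fall outside this rule and were chosen after their values were seen. Alternatives chosen in advance were leaving out each mouse, quantile normalization, median centring, other background limits, the mean of a gene's probe sets or of a list's members, restriction to genes above the limit, all probe sets, and other forms of the variance model. Added after the data were seen were log2(value + 16) for results other than the variance test, list shifts relative to level-matched genes, and removal of a trend on genomic span (lowess, span 0.3). There was no comparison between groups to test.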

Results

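Gene expression was profiled on arrays in the neocortex of CD1 mice, an outbred laboratory stock, at postnatal day 13. The RNA came from 3 wild-type animals. This is the age around eye opening in the mouse, when cortical circuits are forming synapses and myelination is under way. Each animal had 1 array, and the 3 animals formed a single group, so the data describe levels and the spread between animals and hold no contrast between conditions. The arrays reported 23172 probe sets, of which 14938 carried 1 gene name, for 14806 distinct genes. The median intensity was 248.1 for mouse 1, 256.6 for mouse 2 and 230.6 for mouse 3. A level on an array depends on the probes as well as on the RNA, so levels are given gene by gene and no gene is ranked against another. Where a list's median is set against random lists, the probes differ too, so its place among them is a description of these arrays and not a test of expression. The number of arrays limits the precision of every value. All levels are log2 intensities with the SD over mice (n = 3).

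All measured genes of the neuronal marker lists were above the background limit in every mouse, some of them by little. All 11 measured general neuronal markers lay above the background limit on every array, including Snap25 and Syt1, components of the vesicle release machinery, at 12.89 ± 0.10 and 13.18 ± 0.11. Stmn2, a regulator of growing axons, was at 13.15 ± 0.12 and Nefl, the light neurofilament, at 12.11 ± 0.17. The markers of excitatory neurons, 10 of 10 above the limit, included Slc17a7, the cortical vesicular glutamate transporter (12.89 ± 0.10), Camk2a (12.81 ± 0.14), and the transcription factors Neurod6 (10.81 ± 0.51) and Neurod2 (9.74 ± 0.19). All 11 measured markers of layers 2 to 4 were above the limit, with Cux2 at 9.68 ± 0.18, Cux1 at 9.97 ± 0.06, Rorb at 9.78 ± 0.06 and Lhx2 at 10.62 ± 0.22. So were all 12 markers of layers 5 and 6 and the subplate, with Bcl11b at 10.34 ± 0.12, Fezf2 at 10.99 ± 0.17, Foxp2 at 10.09 ± 0.19 and Tle4 at 10.66 ± 0.25. The 13 measured interneuron genes were also all above it. Gad1 and Gad2, which make GABA, stood at 11.68 ± 0.08 and 11.38 ± 0.04, Slc32a1, which loads it into vesicles, at 11.64 ± 0.15, and Pvalb, a calcium buffer of fast-spiking cells, at 10.28 ± 0.24. Against 10000 random gene lists of the same size, the medians of the general neuronal, excitatory and interneuron lists exceeded all of them. The deep-layer median exceeded 9646 and the upper-layer median 8995.

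Glial and vascular genes were measured in the same RNA. Of all single-gene probe sets, 74.6% were above the limit on every array. All 10 measured astrocyte markers were above the limit, with the water channel Aqp4 at 12.20 ± 0.05, Gfap at 11.11 ± 0.15, Aldh1l1 at 10.27 ± 0.24 and the gap junction protein Gja1 at 12.12 ± 0.15. All 12 myelin genes were above it, with Mbp at 12.86 ± 0.10, Mog at 12.56 ± 0.19, Mag at 12.32 ± 0.15 and Mobp at 12.24 ± 0.21. The 10 oligodendrocyte precursor genes were likewise all above it, with Pdgfra at 10.56 ± 0.15, Cspg4 at 8.58 ± 0.33, Olig2 at 9.59 ± 0.10 and Olig1 at 11.30 ± 0.02. The 11 microglial, 11 endothelial and 10 mural markers were all above it too. Among them were Csf1r (10.78 ± 0.04) and Cx3cr1 (9.56 ± 0.08) of microglia, the tight-junction gene Cldn5 (9.63 ± 0.06) of endothelium, and Pdgfrb (9.37 ± 0.32) of pericytes. The myelin median exceeded all 10000 random lists and the astrocyte median 9998 of them. The precursor median exceeded 9450, the microglial median 7716, the endothelial median 6366 and the mural median 4169.

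Genes of synaptic transmission and energy supply were above the limit in nearly all cases. All 13 synaptic vesicle genes were above the limit, with Syp at 13.28 ± 0.13, Syn1 at 11.56 ± 0.07, Syn2 at 12.41 ± 0.04 and Vamp2 at 13.34 ± 0.12. The 12 glutamate receptor subunits, 7 GABA receptor subunits and 9 voltage-gated channel genes measured were all above it. Grin2a and Grin2b, NMDA receptor subunits, were at 9.57 ± 0.33 and 11.66 ± 0.03, Gabra2 and Gabra3 at 10.82 ± 0.10 and 11.96 ± 0.11, and the sodium channel genes Scn1a and Scn8a at 9.67 ± 0.15 and 10.60 ± 0.18. Of the cation-chloride cotransporters, Slc12a5, which extrudes chloride, was at 11.29 ± 0.17 and Slc12a2, which imports it, at 10.06 ± 0.15. The medians of the synaptic vesicle list and of the 12 oxidative phosphorylation genes (Ndufb8 11.65 ± 0.32, Sdha 12.58 ± 0.09) exceeded all 10000 random lists. The glutamate receptor median exceeded 9986, the GABA receptor median 9958, the chloride transport median 9914 and the channel median 9800. The RNA-binding and splicing factors, 10 of 10 above the limit, had a median above 9998 random lists. Rbfox1 was at 12.14 ± 0.13, Rbfox2 at 11.25 ± 0.16, Ptbp1 at 8.98 ± 0.19 and Ptbp2 at 11.56 ± 0.19. In cholesterol synthesis 9 of 10 genes were above the limit, with Hmgcs1 at 12.35 ± 0.06 and Sqle at 11.89 ± 0.07, and the median exceeded 9989 lists. Fdps (6.80 ± 0.26) was above the limit on 2 arrays.

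Genes of newly formed neurons and of dividing cells were both measured. All 9 measured genes of immature neurons were above the limit, with Dcx at 11.08 ± 0.09, Sox11 at 9.05 ± 0.08, Sox4 at 9.69 ± 0.16 and Tubb2b at 12.91 ± 0.08, and their median exceeded 9969 random lists. Of 10 proliferation genes 6 were above the limit on every array, where 74.6% of all single-gene probe sets were. Top2a was at 9.34 ± 0.13 and Cdk1 at 8.23 ± 0.25, Mki67 was above it on 2 arrays (6.81 ± 0.34), and the median exceeded 2190 random lists. Of 14 activity-induced immediate early genes 13 were above the limit, with Fos at 9.57 ± 0.19, Arc at 10.19 ± 0.12, Egr1 at 11.14 ± 0.34 and Junb at 8.17 ± 0.18. Of 10 genes of perineuronal nets, the matrix around some cortical neurons, 9 were above it. Acan, the core aggrecan gene, was above it on 2 arrays at 6.79 ± 0.21, and Bcan, Ncan and Vcan were at 11.93 ± 0.04, 12.24 ± 0.07 and 9.31 ± 0.08.

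Markers of tissue next to the neocortex were measured in the same way. All 9 striatal, 9 thalamic, 10 cerebellar and 8 olfactory bulb genes measured were above the limit, as were 9 of 11 hippocampal ones, and cortical cells also use some of these genes. Drd1 and Drd2, the dopamine receptors of striatal projection neurons, were at 8.92 ± 0.20 and 10.12 ± 0.36, Tcf7l2 of thalamus at 11.46 ± 0.16, Prox1 of hippocampus at 9.19 ± 0.12, Gabra6 of cerebellar granule cells at 9.46 ± 0.18 and Th at 10.43 ± 0.26. The striatal median exceeded 9872 random lists, the cerebellar 9104, the thalamic 8786, the hippocampal 6146 and the olfactory bulb 5167. All 12 meningeal and fibroblast genes were above the limit (Col1a1 10.62 ± 0.46, Col1a2 10.91 ± 0.34), and their median exceeded 9582 lists. Ttr, the main product of choroid plexus epithelium, was at 13.45 ± 0.17, with 5 of 7 choroid plexus and 5 of 6 ependymal genes above the limit. Some genes of cells outside the brain were above the limit too, so lying above it does not by itself show expression in neocortex. The testis, leukocyte and liver medians exceeded 11, 68 and 247 random lists, and 3 of 10, 3 of 8 and 1 of 7 members were above the limit, the liver member being Ttr itself. Of the testis genes, Prm1 (8.99 ± 0.22), Prm2 (7.50 ± 0.14) and Tnp2 (7.48 ± 0.31) were above the limit and Tnp1 (5.73 ± 0.35) was not. Of 7 muscle genes 6 were above it, with Acta1 at 9.85 ± 0.20 and a median above 1121 lists. No globin gene had a probe set of its own here, and of 4 measured red cell genes 2 were above the limit, among them Alas2 at 8.59 ± 0.42.

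**Figure D1:**
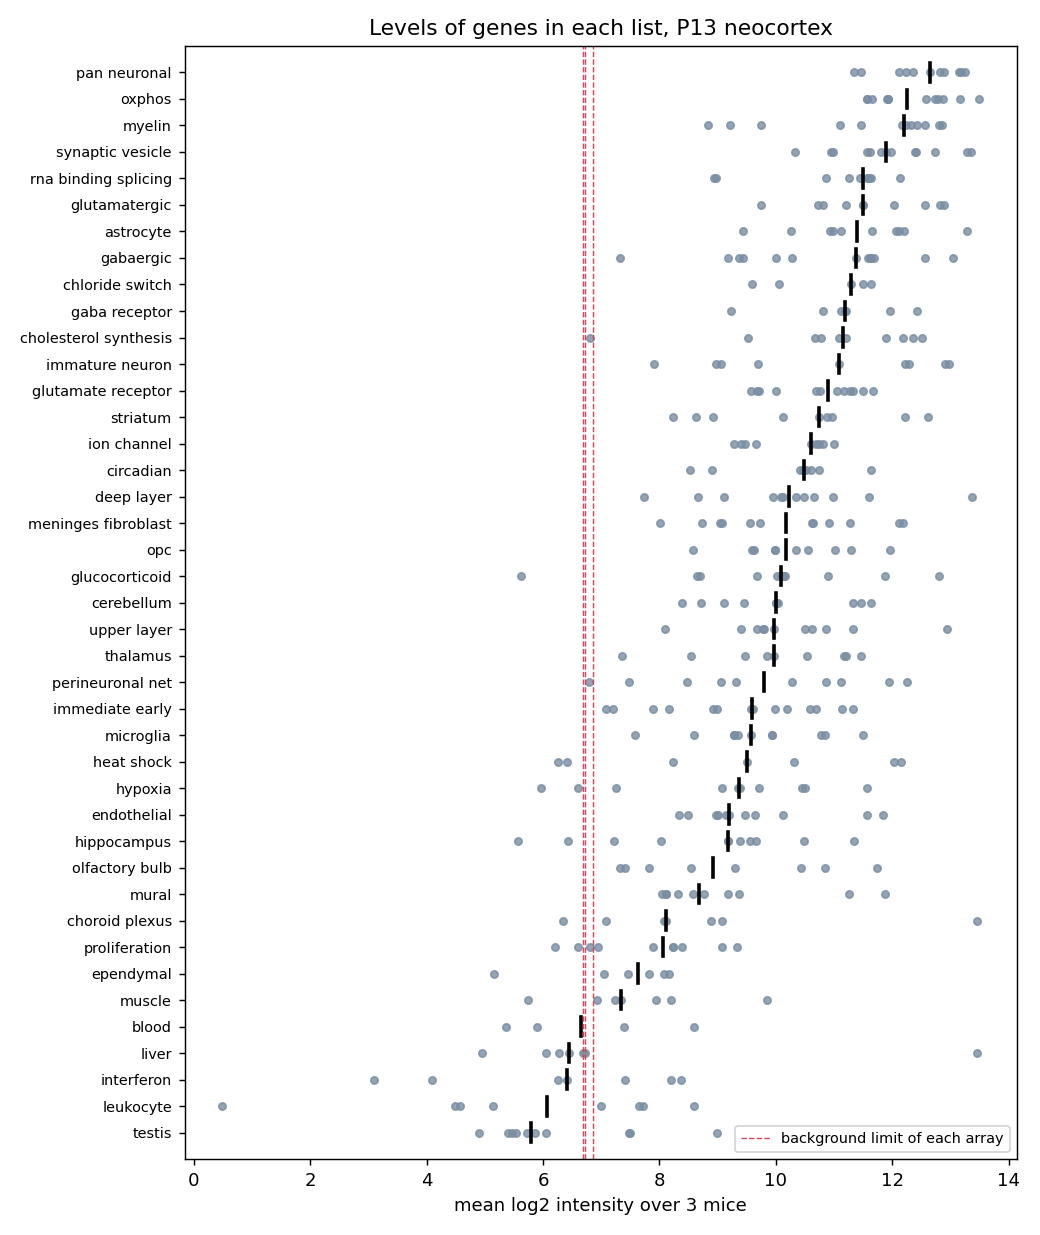
Mean log2 intensity over the 3 mice (horizontal axis) for each measured gene (points) of 41 fixed lists (1 line each), with the list median as a black bar and each array's background limit, 6.86, 6.71 and 6.69 on the log2 scale, as dashed lines. The 11 general neuronal genes lie between 11.34 and 13.24, and 7 of the 10 testis genes were not above the limit on every array.

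The 3 animals resembled each other closely among genes above background. Across the 13811 probe sets above the limit on every array, Spearman's rho between log2 values was 0.979 for mice 1 and 2, 0.981 for mice 1 and 3, and 0.991 for mice 2 and 3, and the lowest Pearson's r was 0.978. Over all 23172 probe sets r was 0.891, 0.887 and 0.887 and Spearman's rho was 0.986, 0.985 and 0.989, in the same order. These correlations run across probe sets, which are not independent replicates. The median SD between mice was 0.16 on the log2 scale, a 1.12-fold spread, with quartiles of 0.10 and 0.24, and 1.32% of the 13811 probe sets had an SD over 0.5. The median probe set was 0.16 higher in mouse 2 than in mouse 1 and 0.05 higher in mouse 3 than in mouse 1. No pair of arrays held identical values. The arrays differed in a level-dependent way, with mouse 1 falling with level and mice 2 and 3 rising. The median deviation of mouse 1 from the mean of the 3 mice was 0.05 in the 2763 dimmest of these probe sets and -0.14 in the 2762 brightest. Mouse 2 ran from 0.06 to 0.11 and mouse 3 from -0.10 to 0.03. The trends are tied together, since all deviations are taken from the same mean. Without mouse 1 the median SD was 0.11.

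Few single genes passed the test for differing between the animals by more than other genes of the same level. On simulated data the test recovered 39% of genes with a 4 times larger SD, so a low count does not show that few genes differed. In limma's robust model of the variance distribution, 9 of 13811 probe sets had an excess variance at a Benjamini-Hochberg adjusted p under 0.05, and 4 of these carried a gene name. Fggy, a member of the carbohydrate kinase family (probe set 6915559), was at 10.02 in mouse 1 against 8.09 and 7.88 in mice 2 and 3, a 4.42-fold difference between the highest and lowest mouse (SD 1.18, adjusted p = 0.000922). Nt5dc3, which encodes a protein with a nucleotidase domain (probe set 6769559), was at 9.93 in mouse 3 against 8.04 and 7.99 in mice 1 and 2, or 3.82-fold (SD 1.10, adjusted p = 0.00241). Rgcc, a regulator of the cell cycle (probe set 6826265), was at 10.07 ± 0.84, with 9.37 in mouse 1, 9.83 in mouse 2 and a level 3.10-fold that of mouse 1 in mouse 3 (adjusted p = 0.0127). Slc15a2, a peptide transporter (probe set 6845444), was at 7.69 in mouse 1 and at 9.12 and 9.26 in mice 2 and 3 (SD 0.87, adjusted p = 0.0459). The other 5 probe sets have no gene name here, and the widest of them, 4499144, was at 9.77, 6.90 and 10.16. At an unadjusted p under 0.05 there were 719 probe sets, where 691 are expected by chance. The model was fitted to these same variances, so a number near the expected one was largely built in. The calls rested on single mice: without mouse 1 the SD of Fggy was 0.15 and that of Slc15a2 0.10, and without mouse 3 that of Nt5dc3 was 0.04 and that of Rgcc 0.32, with adjusted p-values in limma's model between 0.987 and 0.996. Slc15a2 was also lost without mouse 3 (SD 1.01, adjusted p = 0.0854). Of 6 other settings with all 3 mice, Fggy passed in 5 (adjusted p from 0.000964 to 0.0772), Nt5dc3 in 5 (0.00212 to 0.0916), Rgcc in 2 (0.0124 to 0.168) and Slc15a2 in 0 (0.0501 to 0.453). Without mouse 1 the number of probe sets past the threshold was 26, without mouse 2 it was 14, and without mouse 3 it was 10. With all 3 mice it was 2 after quantile normalization and 18 when all probe sets were tested.

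**Figure D2:**
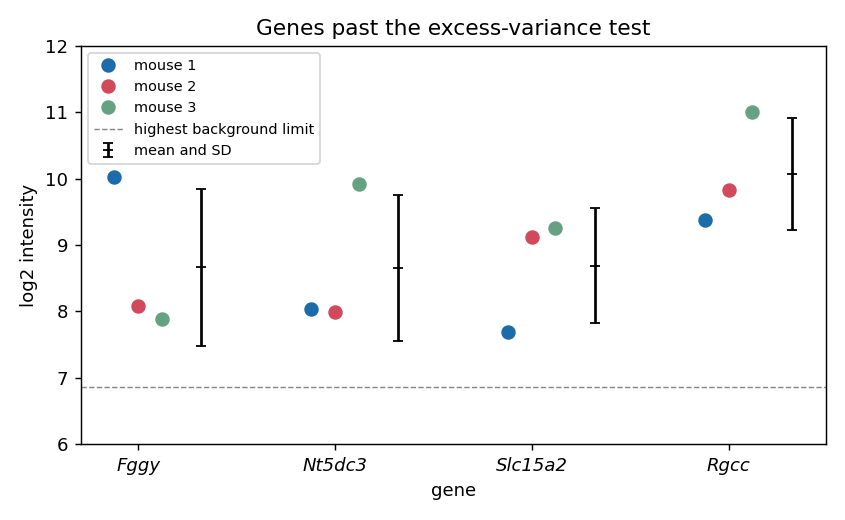
Log2 intensity (vertical axis) of the 4 named genes past the excess-variance test, with 1 point per mouse, the mean and SD of the 3 mice beside them, and the highest of the array background limits (6.86) as a dashed line. Fggy is highest in mouse 1 (10.02), Nt5dc3 (9.93) and Rgcc are highest in mouse 3, and Slc15a2 is lowest in mouse 1 (7.69).

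Of 41 lists, 5 differed together between the mice by more than random lists matched on level, and the median of each of the 5 was lowest in mouse 1 and highest in mouse 2, except that the glucocorticoid median was highest in mouse 3 with each array centred on its median (0.13 in mouse 2 and 0.15 in mouse 3) and with a trend on genomic span removed (0.11 and 0.14). At an unadjusted p under 0.05 there were 6, with the interneuron list (range 0.35, adjusted p = 0.283, permutation of genes). The meningeal and fibroblast list had the widest range of mouse medians over all measured members, 0.57 on the log2 scale against 0.20 for the median random list (adjusted p = 0.0041 from 10000 random lists, a permutation test of genes). All 12 of its genes were highest in mouse 2, among them Mgp, an inhibitor of calcification (8.69, 9.77 and 8.77 in mice 1 to 3), Ptgds, a prostaglandin synthase (11.75, 12.54 and 12.25), and Col1a1 (10.61, 11.08 and 10.16). The striatal list ranged over 0.54 (adjusted p = 0.00683, permutation of genes), and all 9 members were lowest in mouse 1 and highest in mouse 2, with Drd2 at 9.77, 10.48 and 10.10 and Penk, an opioid peptide precursor, at 12.28, 12.81 and 12.73. The microglial list ranged over 0.50 (adjusted p = 0.00615, permutation of genes), and 9 of 11 members were lowest in mouse 1. Aif1, a calcium-binding protein of microglia, was at 8.99, 9.55 and 9.32, while Csf1r was at 10.73, 10.81 and 10.81 and Cx3cr1 at 9.60, 9.61 and 9.48. The immediate early list ranged over 0.41 (adjusted p = 0.0256, permutation of genes), with 11 of 14 members lowest in mouse 1. Egr1 was at 10.88, 11.53 and 11.01, Fos at 9.39, 9.77 and 9.57 and Arc at 10.09, 10.32 and 10.15. Junb, at 7.98, 8.18 and 8.34, was highest in mouse 3. The glucocorticoid-induced list ranged over 0.41 (adjusted p = 0.0303, permutation of genes), with 11 of 12 members lowest in mouse 1, Fkbp5 being at 9.48, 9.83 and 9.73 and Tsc22d3 at 9.88, 10.30 and 10.12. Sgk1 was highest in mouse 3 (10.70, 10.95 and 11.05), and Per1 was the member not lowest in mouse 1 (10.11, 10.36 and 9.94). Over all measured genes above the limit, 53.5% were lowest in mouse 1 and 59.5% highest in mouse 2.

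The median member was 1.46-fold higher in mouse 2 than in mouse 1 in the meningeal list and in the microglial list, 1.44-fold in the striatal list, 1.33-fold in the glucocorticoid list and 1.26-fold in the immediate early list. These folds include a shift that level-matched genes share. Relative to those genes the range was 0.38 for the meningeal, 0.33 for the microglial, 0.34 for the striatal, 0.25 for the immediate early and 0.22 for the glucocorticoid list. No single member passed the excess-variance test over all genes in limma's model. Adjusted over the list alone, 3 of 12 meningeal, 1 of 11 microglial, 0 of 9 striatal, 0 of 13 immediate early and 0 of 11 glucocorticoid genes did, and 4, 2, 3, 1 and 1 had an unadjusted p under 0.05. The endothelial list was split: its median lay 0.15 above the mean of the 3 mice in mouse 1, where level-matched genes lay below it, 6 of its 11 genes were highest and 5 lowest in that mouse, and its range of 0.18 did not pass (adjusted p = 0.986, permutation of genes). Over the members above the limit alone, the 3 leukocyte genes left, Cd3e, S100a8 and Camp, also passed, with a range of 0.90 and the highest median in mouse 1 (adjusted p = 0.0175, permutation of genes), against 0.42 over all 8 (adjusted p = 0.795). Cd3g and S100a9 of the same list were under the limit on every array, so these 3 genes do not by themselves show a difference in leukocytes. Each of the 5 calls needed both mouse 1 and mouse 2, and the immediate early call needed mouse 3 as well. Without mouse 1 no list passed and 5 of 41 had an unadjusted p under 0.05, without mouse 2 no list passed and 6 did, and without mouse 3 the meningeal, striatal, microglial and glucocorticoid lists passed and the immediate early list did not (range 0.34, adjusted p = 0.189, permutation of genes). With each array centred on its median, the immediate early and glucocorticoid lists did not pass (adjusted p = 0.0533 and 0.0672, permutation of genes), and over 8 other settings with all 3 mice their adjusted p ran from 0.0170 to 0.0533 and from 0.0238 to 0.0672.

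**Figure D3:**
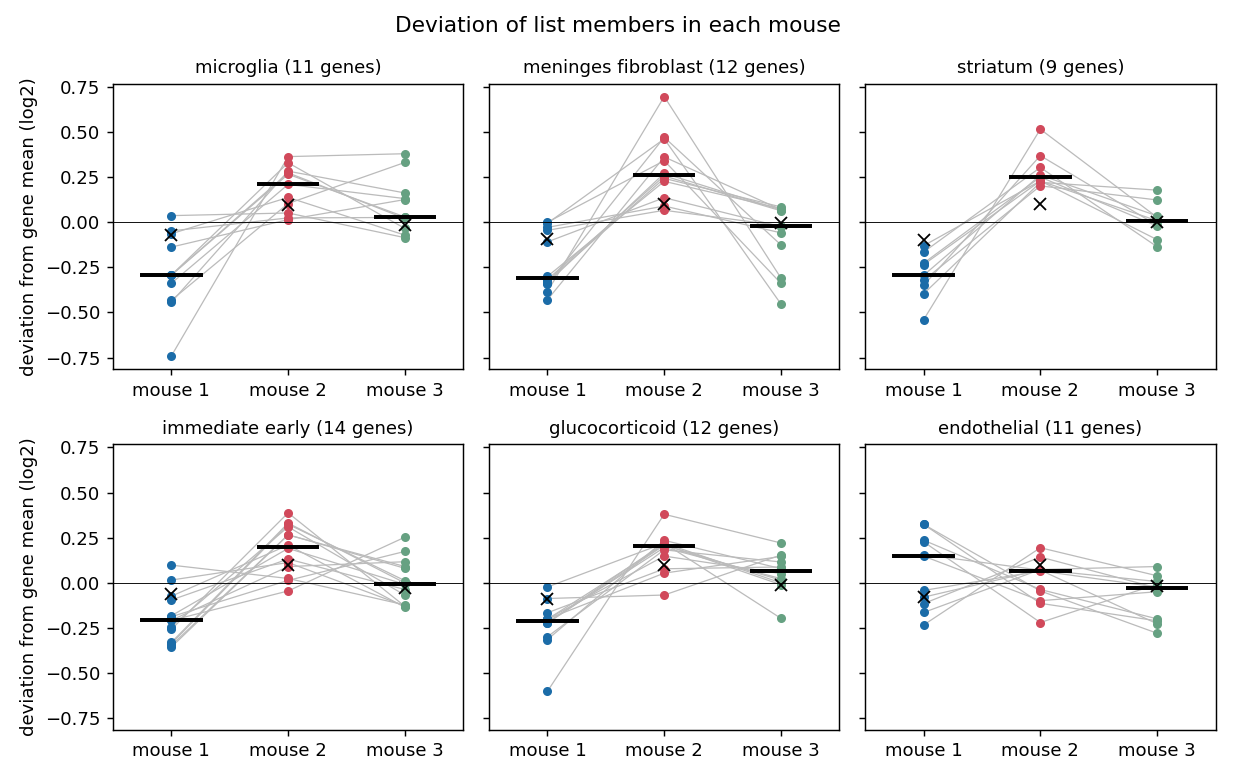
Deviation of each gene from its own mean over the 3 mice on the log2 scale (vertical axis) in mice 1, 2 and 3 for the 5 lists that passed and for the endothelial list, with 1 line per gene, the list median as a black bar and the median of level-matched random lists as a cross. The medians of the 5 lists lie between -0.31 and -0.21 in mouse 1 and between 0.20 and 0.26 in mouse 2, and the endothelial median is 0.15 in mouse 1.

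The labels do not give the sex of the animals. Of the sex-linked list, the Y-linked genes Kdm5d and Eif2s3y had a probe set of their own. Neither was above the limit on any array. Kdm5d was at 5.67, 5.46 and 5.36 in mice 1, 2 and 3, and Eif2s3y at 2.48, 2.93 and -1.30. Xist, the X-inactivation transcript, was not analysed here.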

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

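Of the alternatives, log2(value + 16) outside the variance test, shifts relative to level-matched genes and removal of the span trend were chosen after seeing the data. The number of lists with a level at or above the 95th percentile was 18, except with the mean over members, which gave 25. The number of probe sets above the limit, 13811, became 11163 with the 99th percentile limit and 14532 when 2 arrays sufficed. Both numbers stayed within 1.5 times under every alternative run. The lowest Pearson's r between arrays, 0.887 over all probe sets, was 0.978 over those above the limit and 0.985 with log2(value + 16), and leaving out a mouse gave 0.887 to 0.891. The median SD of 0.16 became 0.23 over all probe sets, and 0.11 to 0.17 with a mouse left out. The 9 probe sets with excess variance became 2 after quantile normalization and 18 when all probe sets were tested, and 10 to 26 with a mouse left out. The cause was not tested. The 5 list shifts became 8 after quantile normalization, 3 with median centring and 11 relative to level-matched genes, and 0 to 4 with a mouse left out. All 5 were among the 8 and the 11. Restricted to members above the limit there were 6, the 5 and the leukocyte list, whose 3 genes had a range of 0.90 and ran the other way. With median centring the immediate early range was 0.36 (adjusted p = 0.0533) and the glucocorticoid range 0.38 (adjusted p = 0.0672), each from the permutation of genes. With a mouse left out, the ranges were 0.15 to 0.55 for the meningeal, 0.12 to 0.55 for the microglial, 0.27 to 0.52 for the striatal, 0.19 to 0.34 for the immediate early and 0.16 to 0.41 for the glucocorticoid list. The glucocorticoid median was highest in mouse 3, not mouse 2, with median centring and with the span trend removed. Every alternative chosen in advance was run. No paired analysis was possible because the series holds 1 group. Signal over background limits the dim genes: the larger median SD over all probe sets comes with those below the limit.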

Other observations

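The tests of the intensity-dependent difference and of cell shares on the 5 lists, the shifts relative to level-matched genes, and the choice of Glo1 and Btbd9, came after the results were seen. The tests of genomic span, of adjacent pairs and of the segment around Glo1 were also added after the data were seen, but before their own results.

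Several programs not described above were also measured. All 8 circadian clock genes measured were above the background limit, with Dbp at 10.75 ± 0.09, Per3 at 8.53 ± 0.10, Nr1d2 at 10.61 ± 0.06 and Arntl at 10.51 ± 0.19 (SD, n = 3), and their median exceeded 9718 of 10000 random lists. Of 10 hypoxia-induced genes 8 were above it, with Vegfa at 10.45 ± 0.14 and Bnip3 at 10.50 ± 0.11, and a median above 7033 lists. Adm (6.60 ± 0.43) was above the limit on 1 array and Car9 (5.96 ± 0.20) on 0 arrays. Of 7 heat shock genes 5 were above it, with Dnajb1 at 10.30 ± 0.24 and Hsph1 at 12.02 ± 0.13, and a median above 7064 lists. Hsp90aa1 (6.41 ± 0.58) was above the limit on 1 array and Hspa1a (6.25 ± 0.57) on 0 arrays. Of 12 glucocorticoid-induced genes 11 were above it, and the median exceeded 9438 lists; for the immediate early list that number was 8133 and for perineuronal nets 8581. Of 7 interferon-induced genes 3 were above it, Ifit1 was below it on every array at 4.09 ± 0.53, and the median exceeded 242 lists. The choroid plexus, ependymal and red cell medians exceeded 2722, 1710 and 734 lists.

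Relative to level-matched genes, 6 further lists differed between the mice. The myelin median differed from matched genes by -0.14 in mouse 2 and by 0.14 in mouse 3, a range of 0.28 (adjusted p = 0.00205, permutation of genes), and 11 of 12 myelin genes were highest in mouse 3. As the values stand its range did not pass (adjusted p = 0.795, permutation of genes), nor did that of the channels (0.391). The list of voltage-gated channels was 0.27 above matched genes in mouse 1 (adjusted p = 0.00273 for its range, permutation of genes), with 7 of 9 genes highest in that mouse. The glutamate receptor, excitatory neuron, synaptic vesicle and endothelial lists were also highest in mouse 1 by this measure. The adjusted p-values of their ranges were 0.0301, 0.0395, 0.0496 and 0.0496 (permutation of genes). As the values stand none of them passed (adjusted p from 0.986 to 0.995, permutation of genes). Of these 6 lists, the myelin, channel and glutamate receptor lists also passed after quantile normalization. S100a8, a granulocyte calcium-binding protein, was at 7.65 ± 0.98, with 8.78 in mouse 1, 7.19 in mouse 3 and the lowest level in mouse 2, 3.44-fold under mouse 1, and Cox6a1 of the respiratory chain at 12.38, 13.55 and 13.56, both with an adjusted p of 0.0617 in limma's model. S100a9, of the same list as S100a8, was under the limit on every array at 5.09, 5.22 and 5.09.

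The meningeal, striatal, microglial, immediate early and glucocorticoid lists were all lowest in mouse 1. After quantile normalization 5 of the 5 lists passed again. The ranges became 0.34, 0.32, 0.32, 0.28 and 0.23, in that order, from 0.57, 0.54, 0.50, 0.41 and 0.41. Part of the shift was thus removed. The 5 lists were chosen by a test against random lists matched on level, which would share an intensity-dependent difference between arrays. Passing again was therefore likely from the start. It adds little against such a difference as the whole cause. The values show only that these ranges exceeded those of level-matched lists, before and after the normalization. A trend with genomic span as the whole cause is argued against, since 5 of 5 lists passed with that trend removed. The ranges were then 0.44, 0.45, 0.38, 0.27 and 0.31. A smaller share of non-neuronal cells in mouse 1 would lower the endothelial list there, but that list lay 0.23 above level-matched genes. It exceeded 99.97% of random lists, past the mark set for excluding this cause. However, 6 of its 11 members were highest in mouse 1 (Kdr 10.44, 10.07 and 9.83) and 5 lowest, so its median does not speak for all members. The astrocyte, mural, myelin and precursor medians differed from matched genes by -0.02, -0.04, 0.03 and 0.08, which shows no clear lowering. The striatal list, of markers of neurons, differed from matched genes by -0.19 in mouse 1, which this cause would not give. As the whole cause of the 5 shifts it is thus argued against, and as a part of the cause it stays open. Also open and untested are the line of dissection, which could bring meninges and striatum together, RNA quality or transcript length, for which no values were at hand, and handling of the animals. The 5 lists share 0 members with the other lists, but cortex also expresses many of them. No biological explanation was tested, since the design names no difference between the mice and there is no group comparison.

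Glo1, a glyoxalase that detoxifies methylglyoxal, was at 7.77, 9.25 and 8.44 in mice 1, 2 and 3, and its neighbour Btbd9 at 10.44, 11.72 and 11.02, so that both differed 2.79-fold and 2.43-fold between mice 1 and 2 with mouse 3 between them. Neither passed the variance test (adjusted p = 0.185 and 0.138 in limma's model). After quantile normalization the range of each exceeded 100% of the 500 genes nearest in level, so genes of like level did not share these ranges. Both genes were chosen after their values were seen, so this outcome was likely from the start. It adds little against an intensity-dependent difference between arrays. A chance pair stays open: among the 110 most variable of 11043 placed genes there were 3 adjacent pairs, against a mean of 1.10 in 10000 random draws (p = 0.0988, one-sided permutation test). A copy number difference is a further hypothesis, since a duplication that holds Glo1 and part of Btbd9 is known to vary among mouse stocks, but only 1 of its other 2 genes was above the limit on every array, and Glp1r (8.54, 8.73 and 8.33) had a range of 0.40, below what the hypothesis needed and above what would exclude it, and was lowest in mouse 3, not in the order of mice the hypothesis needed, while Dnah8 was at 5.47, 6.80 and 5.49.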
